A study of Strongylocentrotus purpuratus with 8 samples.

How the data were processed

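Dissociated embryos of the purple sea urchin, Strongylocentrotus purpuratus, were measured at 8 stages: 8-cell, 64-cell, morula, early blastula, hatched blastula, mesenchyme blastula, early gastrula and late gastrula. Each stage was 1 library made with droplet-based 3′ chemistry (10x Chromium, version 3) and sequenced on an Illumina HiSeq. Several fertilizations were timed so that all stages were reached at a common end point, and equal numbers of embryos went into each time point. With 1 library per stage, stage, fertilization and library cannot be told apart, and no test, p-value or standard error between stages was computed.

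The deposited matrices hold whole-number UMI counts per gene and barcode, where a UMI (unique molecular identifier) stands for 1 captured transcript molecule. The submitters' notes name Cell Ranger and Seurat 3.1.4, and per the file headers the counts were written by software version 3.0.2. The genome build and the annotation behind the counts are not given in the sources used here. For the 4 latest stages the barcodes carried 2 well suffixes, and these wells were treated as technical portions of 1 library, not as replicates. How the wells' depths were set is not given in the sources used here.

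The feature table held 32262 genes, of which 21089 were found in the reference table of gene names. Of all features, 30894 had a locus identifier as their only name, 1024 were tRNAs and 344 had another name. Genes are named here as in the feature table, except 3 names taken from the reference table, among them SpAN and prox1. No coordinates were used. The 63 microRNA loci in the table had 0 UMIs in every library, so microRNAs were not analysed further here.

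Barcodes with at least 200 detected genes were kept, which removed none. UMIs were summed over the kept barcodes of each library and expressed as counts per 1000000 UMIs of the library (CPM). A pseudocount of 1 CPM was added before log2 ratios were taken. A gene was called higher or lower when the ratio on this scale was at least 4-fold and the higher library had at least 50 CPM. The 7 steps between adjacent stages and late gastrula against 8-cell were compared, giving 8 comparisons. Folds printed for single genes are ratios of CPM with exact Poisson 95% intervals. For a gene with 0 UMIs in 1 library, the fold is a lower bound computed from a floor of 3 counts in that library. Intervals and floors cover counting error only.

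The genes named for each comparison were the 5 with the largest increase and the 5 with the largest decrease among those with a name other than a locus identifier and at least 50 CPM in the higher library, together with the measured members of fixed gene lists and the 5 leading genes of each cluster class at late gastrula. Not every gene named by this rule passed 4-fold. The lists covered skeletogenic mesenchyme, pigment cells, blastocoelar cells, coelomic pouch and muscle, germline, endoderm, oral ectoderm, aboral ectoderm, apical plate and neural cells, ciliary band, early zygotic genes, egg cortical genes, maternal and cell cycle genes, signalling, ciliogenesis, histones, ribosomal proteins, mitochondrial genes, stress genes, sperm and coelomocytes. Many members did not match a name in the feature table: 8 of 22 skeletogenic genes matched, 6 of 13 endoderm, 7 of 11 oral, 11 of 15 aboral, 3 of 15 apical, 5 of 8 blastocoelar, 3 of 5 ciliary band, 7 of 12 early zygotic and 3 of 6 ribosomal genes. The pigment list matched 1 of 7, the coelomic pouch and muscle list 1 of 10, the germline list 2 of 6, the egg cortical list 2 of 9, the maternal and cell cycle list 1 of 26, the signalling list 3 of 26, the ciliogenesis list 1 of 25, the sperm list 1 of 8 and the coelomocyte list 2 of 8. None of 5 histone, 13 mitochondrial and 13 stress names matched, so those lists gave no value. One gene is not reported here. For each list and step, members that changed at least 2-fold with at least 10 CPM in the higher library were counted. The list's median log2 ratio was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. Where members had 0 UMIs, the median was also taken with them at the floor.

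The barcodes of each stage were clustered on their own. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours fed a graph of shared neighbours, weighted by the Jaccard index, that was partitioned with the Leiden algorithm at resolution 1. A cluster was given a class name when at least 3 of that class's markers were raised in it and it had more of them than of any other class. A marker counted when its CPM plus 10, over the same quantity in the other cells, was at least 2-fold, with at least 10 UMIs in the cluster and detection in at least 5% of its cells. A cluster stayed unnamed when a marker of another class reached 90% of the fold of its own best marker. These numerical limits were set after the data had been seen, whereas the markers themselves were fixed earlier. Names therefore mean that a cluster resembles a class in these genes. Leading genes had to be detected in at least 25% of the cluster's cells, and no named cluster had more markers of another class than of its own among its 10 leading genes. Shares of cells carry exact Clopper-Pearson 95% intervals.

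Shares of cells with a UMI of a marker were computed after thinning every cell to 1000 UMIs and leaving out shallower cells, which concerned 836 hatched blastula barcodes. Beside each share stands the share in a class that should lack the gene, since free RNA in the droplets gives UMIs in cells that do not express a gene. Genes whose variance between cells exceeded Poisson sampling were counted in 950 cells per stage, thinned to 1000 UMIs, as those with a variance-to-mean ratio (Fano factor) of at least 1.5 and a mean of at least 0.05 UMI.

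The steps were tested on simulated data. With 200 genes changed 8-fold, all 200 were called in each of the 8 comparisons, out of 2705 to 3410 genes considered, and no other gene was called. With 200 genes changed 2-fold, 0 were called. With 200 genes made variable at equal depth, the variance rule called 106 of them with the expression profile of the 8-cell library. With that of late gastrula it called 72, with 4 and 3 other genes, so it misses moderate variation. Of 200 random lists, 191 ranked between the 2.5th and 97.5th percentile. In 1000 simulated late gastrula cells, 100 of 100 skeletogenic cells were named as such and 0 others. Those 100 cells were made by strongly raising the naming markers themselves, at equal depth and without free RNA. The outcome was thus nearly built in and does not tell how well real clusters were named.

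The thresholds, comparisons, lists, naming rule for genes and most alternatives were chosen before the data were examined. The alternatives were TMM factors of edgeR 4.0.16 and median-of-ratios factors of DESeq2 1.42.0 in R 4.3.3, a pseudocount of 5 CPM, a minimum of 10 CPM or none, all deposited barcodes, at least 1000 genes per barcode, the mean of each cell's CPM, each well alone, resolutions of 0.5 and 2, 4000 variable genes, doublets marked by Scrublet left out, thinning to 2000 UMIs or none, and a Fano factor of 2. Further alternatives were chosen after seeing the data: the lowest UMI total of the late gastrula library (2475) as a minimum in every library, the highest 5% of doublet scores left out, and the 64-cell library without a cluster of 42 barcodes. Scrublet marked 0.632% of 8-cell, 2.70% of 64-cell, 0.622% of morula, 0.109% of early blastula, 0.112% of hatched blastula, 0.0984% of mesenchyme blastula, 0.169% of early gastrula and 2.79% of late gastrula barcodes. Its automatic threshold may have failed where few were marked, which was not tested. The other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.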

Results

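Transcripts of single cells were counted in sea urchin embryos at 8 stages from 8-cell to late gastrula, with 1 library per stage and no replicates. The libraries held 950 barcodes at 8-cell, 1000 at 64-cell, 3700 at morula, 6400 at early blastula, 12504 at hatched blastula, 12200 at mesenchyme blastula, 13000 at early gastrula and 13000 at late gastrula. Total depth was 15287975 UMIs at 8-cell, 29777965 at 64-cell and 42872261 to 48297861 at the other stages. A median barcode held 11904.5, 32493, 11559, 6066.5, 3466.5, 3686.5, 3406 and 3190 UMIs from the earliest to the latest stage, and a median of 3553, 5931, 3608, 2310.5, 1458, 1484, 1431 and 1375 genes. A floor of 3 counts corresponded to 0.196 CPM at 8-cell, 0.101 CPM at 64-cell and 0.0621 to 0.0700 CPM later. The lowest UMI total of any barcode differed between libraries, at 4042, 2615, 3834, 2409, 410, 1201, 1297 and 2475. Between the wells of the 4 latest stages, 0 genes differed 4-fold, and 8 of 2850, 4 of 2764, 0 of 2853 and 11 of 2740 genes differed 2-fold.

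From 8-cell to 64-cell, a few regulators of later lineages, with HE and SpAN, went up, while most members of the lineage lists did not. PMAR1, a homeobox repressor that acts in the micromeres, rested on 3 UMIs at 8-cell and stood at 14.0 CPM at 64-cell, a ratio of 71.2 (95% Poisson interval 24.2 to 347). Alx1, which drives skeletogenic fate, was 20.5-fold higher (11.6 to 39.9), and eve, expressed in vegetal cells, was 48.9-fold higher (27.2 to 98.2). HE, the hatching enzyme, and SpAN, a protease of the astacin family, had 0 UMIs at 8-cell and were at least 62.3-fold and at least 59.0-fold higher at 64-cell. Both had far higher levels in 42 barcodes, in which SpAN had 445 CPM against 2.84 CPM in the other 64-cell barcodes, and HE had 297 against 6.48 CPM. The other barcodes were also above the 8-cell floor of 0.196 CPM, so the rise was not confined to the 42. Genes called 4-fold higher numbered 12 and genes called lower 0, of 3666 considered, and all 12 carry only a locus identifier. Among other named genes with at least 50 CPM the shifts were smaller. SLBP, which binds histone mRNA, was 2.00-fold higher (1.95 to 2.05), SRC8 was 2.17-fold, kap115 2.05-fold, NADK 1.98-fold and KRP85 1.87-fold higher. MTB1, a metallothionein, was 3.11-fold lower (2.94 to 3.29), egf1 2.55-fold, duox1 1.99-fold, MTa 1.64-fold and Sp-Smad2/3 1.60-fold lower. In the early zygotic list, 3 of 7 members rose at least 2-fold and 0 fell, with a median log2 ratio of 2.62, or 5.02 with unseen members at the floor, above all random lists. HE and SpAN belong to this list, and outside the 42 barcodes both lay under its limit of 10 CPM. The list was not recomputed without those barcodes, so its count of higher members depends partly on them. Members higher at least 2-fold were 1 of 7 skeletogenic, 1 of 5 endoderm, 1 of 3 apical, 0 of 7 oral, 0 of 9 aboral, 0 of 4 blastocoelar and 0 of 3 ciliary band genes, and 0 were lower. The 3 ribosomal protein genes had a median of -0.50 and none passed 2-fold.

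At morula, regulators of ectoderm, endoderm and skeletogenic mesenchyme were far higher than at 64-cell. Across this step, 154 of 3814 genes were called higher and 107 lower. VEB4 rose 37.0-fold (32.9 to 41.7), from 9.54 to 353 CPM. Not, an oral ectoderm homeobox gene, rose 42.2-fold (34.2 to 52.7), Hbox7 25.4-fold (19.7 to 33.5) and EGF2 25.4-fold (20.3 to 32.1). No oral class was named at morula, so the rise of Not cannot be placed in oral cells. After thinning to 1000 UMIs, 20.3% of morula endoderm cells had a UMI of Not, against 10.9% of all cells. MMP14, a matrix metalloproteinase, rose 41.6-fold (30.5 to 58.4). Alx1 reached 207 CPM, 12.9-fold above 64-cell (11.7 to 14.1), foxq2, an apical plate gene, was 11.3-fold higher (10.3 to 12.4), blimp1/krox, an endoderm regulator, 14.3-fold (12.8 to 15.95) and eve 14.7-fold (13.8 to 15.6). SpAN was 17.5-fold higher (15.7 to 19.6) and HE 13.7-fold (12.3 to 15.2). The largest decreases among named genes were in eef1Bb, 10.3-fold (9.61 to 11.03), p160, 5.51-fold, and Tcf/Lef, which carries Wnt signals to DNA, 4.88-fold. Sp-Smad2/3 was 2.96-fold and kap115 2.06-fold lower. List medians were 1.19 for early zygotic genes (4 of 7 higher), 2.77 for endoderm (2 of 5), 2.07 for oral ectoderm (2 of 7; 3.59 with the unseen member at the floor), 1.55 for the apical plate list (1 of 3; 3.69), 0.77 for aboral ectoderm (2 higher and 1 lower of 9) and 1.06 for skeletogenic genes (1 of 7; 3.35). FoxJ1, the only matched ciliogenesis gene, was 14.3-fold higher (12.2 to 16.8).

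Between morula and early blastula, several gut and pigment cell regulators rose, while Ets4, Tcf/Lef and SLBP were among the genes that fell. GATAe, an endomesoderm regulator, rose from 0.995 to 56.0 CPM, 56.3-fold (42.0 to 77.5). FoxA, needed for endoderm, rose 27.6-fold (24.7 to 30.9) and gcm, the pigment cell regulator, 31.4-fold (27.0 to 36.6). ARS, an arylsulfatase of the aboral ectoderm, rose 32.9-fold (30.8 to 35.1) and SpP19L, a skeletogenic gene, 32.2-fold. Ets4 fell 27.6-fold (24.9 to 30.7), Tcf/Lef 18.5-fold, isg12 9.08-fold, SLBP 8.78-fold and SLC12A2 5.08-fold. PMAR1, with 11.5 CPM at morula, was 8.06-fold lower at 1.42 CPM. Of 3763 genes, 256 were called higher and 249 lower, and this balance depended on the scaling: the higher share was 50.7% with CPM, 74.4% with TMM factors (378 higher, 130 lower) and 73.4% with median-of-ratios factors (380 and 138). Endoderm genes had a list median of 3.36 (4 of 5 higher), oral ectoderm genes 1.24 (4 of 7) and apical plate genes 1.91 (2 of 3). Early zygotic genes split, with 3 of 7 higher, 2 lower and a median of 0.22. In the skeletogenic list, 0 of 7 members passed 2-fold, with a median of 0.47. The median was 0.07 for aboral genes (3 of 9 higher), 0.06 for blastocoelar genes (1 higher, 2 lower of 4) and -0.19 for ciliary band genes (1 of 3 lower), while the ribosomal proteins had a median of 2.58 with 3 of 3 higher. The signalling list, with 2 measured members, had a median of 1.08 and 1 member higher.

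Across hatching, HE and SpAN declined while most aboral ectoderm and several skeleton genes increased. HE fell 32.3-fold between early and hatched blastula (29.5 to 35.3), from 353 to 10.96 CPM, and SpAN fell 4.29-fold (4.17 to 4.41). VEB4 fell 18.0-fold, foxx 27.9-fold, BACE 9.53-fold and Cdc6, a DNA replication factor, 8.87-fold. In the opposite direction, Tbx2/3, an aboral ectoderm regulator, rose 114-fold (98.7 to 133) and NK2.2 79.8-fold (68.8 to 93.3). The spicule matrix gene PM27 rose 39.0-fold (31.9 to 48.2), SM50 13.01-fold (11.5 to 14.8) and msp130, a skeletogenic cell surface protein, 15.8-fold (14.0 to 18.0). CyI, a cytoskeletal actin, rose 24.0-fold and Endo16, a gut differentiation gene, 17.7-fold. There were 239 genes called higher and 283 lower of 3544, a higher share of 45.8% that became 56.0% with TMM factors and 49.3% with median-of-ratios factors. Aboral genes had a list median of 2.81 (8 of 9 higher), skeletogenic genes 3.49 (4 of 7), blastocoelar genes 2.13 (3 of 4), oral genes 1.70 (3 of 7), endoderm genes 0.63 (2 of 5), apical genes 0.17 (1 of 3) and ribosomal proteins 2.27 (3 of 3). The early zygotic median was -1.19, with 4 of 7 lower.

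Few genes changed from hatched to mesenchyme blastula, the period in which skeletogenic cells enter the blastocoel. Of 2879 genes, 0 were called higher and 3 lower: SpAN, which fell 6.66-fold (6.21 to 7.15), and LOC752524 and LOC105438238, which were picked out after their values were seen, with decreases from 176 to 19.5 CPM and from 142 to 27.7 CPM. Below the 4-fold limit, SM37 was 3.23-fold higher (3.09 to 3.38), SM50 2.85-fold, PM27 2.80-fold, hox1 2.998-fold and FoxG 2.21-fold. MMP14 was 3.22-fold lower, dri 1.92-fold, SRC8 1.75-fold and DVR1 1.68-fold. Skeletogenic genes had a list median of 1.48 with 4 of 7 higher, or 0.91 when the minimum of 2475 UMIs was applied to every library. Medians of the remaining lists with at least 2 measured genes lay between -0.54 for early zygotic genes (2 of 7 lower) and 0.48 for ribosomal proteins (none past 2-fold).

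At early gastrula, SM30A, dri and several transcripts later high in endoderm increased, while no member of the endoderm list passed 2-fold. SM30A, a spicule matrix gene, rose 20.2-fold over mesenchyme blastula (18.9 to 21.6), from 19.3 to 389 CPM, and dri rose 5.87-fold (5.64 to 6.11), from 58.6 to 344 CPM. LOC589852, LOC591984 and LOC575684, later among the leading genes of endoderm, rose from 0.456 to 56.1 CPM, from 3.87 to 127 CPM and from 28.6 to 378 CPM. These transcripts, SM30A and dri were among 15 genes called higher of 2928, and MMP14, which fell 6.997-fold (6.46 to 7.58), was among 6 called lower. Increases of other named genes with at least 50 CPM stayed under 4-fold, at 2.35-fold for SM37, 2.23-fold for FoxG and 2.14-fold for SM50. GATAc was 2.95-fold lower (2.77 to 3.14), SFRP 2.78-fold, Alx1 2.42-fold and HMG1 2.38-fold. The skeletogenic list thus moved both ways, with 3 of 7 members higher, 1 lower and a median of 0.98, which became 0.29 with the minimum of 2475 UMIs. Blastocoelar genes had a median of -0.72 (1 of 4 lower), apical genes -0.59, ciliary band genes 0.69 (1 of 3 higher), oral genes 0.36 (2 of 7 higher), aboral genes 0.21 (1 of 9 higher), endoderm genes 0.30 and early zygotic genes -0.42 (1 of 7 lower).

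Between early and late gastrula all called genes were lower, among them skeletogenic and collagen genes. SM50 fell 4.48-fold (4.34 to 4.62), PM27 4.03-fold (3.91 to 4.15), and the collagens COLP3alpha and COLP4alpha (gene26446) fell 4.68-fold and 5.01-fold (4.77 to 5.27). These were among 11 genes called lower of 2853, with 0 called higher. Those calls did not hold once both libraries had the same minimum of 2475 UMIs per barcode, which left 0 genes called: SM50 was then 1.67-fold lower (1.61 to 1.73), PM27 1.67-fold, msp130 1.70-fold in place of 3.59-fold, and COLP4alpha (gene26446) 2.42-fold. SM30A changed direction, from 1.23-fold lower to a ratio of early to late gastrula of 0.499 (0.484 to 0.514). Alx1 was 2.47-fold lower without the minimum and 2.03-fold with it. Among increases, mvp was 2.74-fold higher (2.62 to 2.86), dri 2.37-fold, eef1Bb 1.56-fold, GATAe 1.48-fold and FSCN1 1.46-fold, none past the limit. The skeletogenic median was -1.83 with 6 of 7 lower, or -0.74 with the minimum. Blastocoelar genes had a median of -1.07 (3 of 4 lower), or -1.03 with the minimum. Endoderm had 0.19 and apical genes 0.22. The oral and aboral medians were both -0.05 and both 0.07 with TMM factors, so their direction was not settled.

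**Figure D1:**
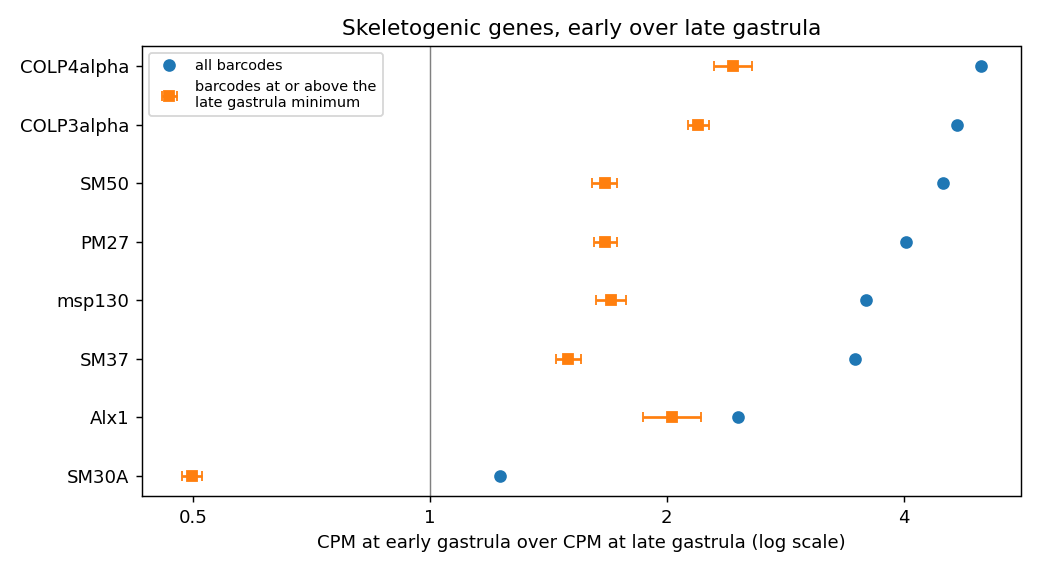
Ratio of early to late gastrula CPM (log axis) for skeletogenic genes, with all barcodes (circles) and with the late gastrula minimum of UMIs per barcode in both libraries (squares), bars giving 95% Poisson intervals. SM50 moved from 4.48 to 1.67 and SM30A from 1.23 to 0.499.

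Over the whole series, several ectoderm, gut and skeleton transcripts rose, and CycA, Ets4, foxx and Cdc6 fell. EGF2 rose 4381-fold from 8-cell to late gastrula (3119 to 6364), ARS 2380-fold (1884 to 3054) and SPEC1, a calcium-binding protein of the aboral ectoderm, 1624-fold (1116 to 2464). Each of dri and FoxA rested on 1 UMI at 8-cell, with ratios of 12466 (2237 to 492413) and 9611 (1725 to 379630). Endo16 had 0 UMIs at 8-cell and was at least 2601-fold higher, as were SM30A at least 1614-fold, FoxG at least 799-fold, PM27 at least 623-fold, SM37 at least 573-fold, SM50 at least 531-fold and msp130 at least 370-fold. CycA, cyclin A, fell 32.1-fold (31.5 to 32.7), from 8357 to 260 CPM, Ets4 fell 55.8-fold (49.4 to 63.3), foxx 40.1-fold and Cdc6 30.1-fold. For p160, with 3 UMIs at late gastrula, the ratio was 1595 (545 to 7742). Of 4212 genes, 747 were called higher and 1133 lower, a higher share of 39.7% that became 60.1% with TMM factors (979 and 651) and 52.8% with median-of-ratios factors (896 and 801). TMM and median-of-ratios factors moved the median of all genes by 0.51 and 0.34 in this comparison. The corresponding shifts were -0.12 and -0.18 from 8-cell to 64-cell, 0.15 and 0.16 to morula, 0.34 and 0.33 to early blastula, 0.15 and 0.06 to hatched blastula, -0.12 and -0.14 to early gastrula and 0.12 and 0.12 to late gastrula.

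**Figure D2:**
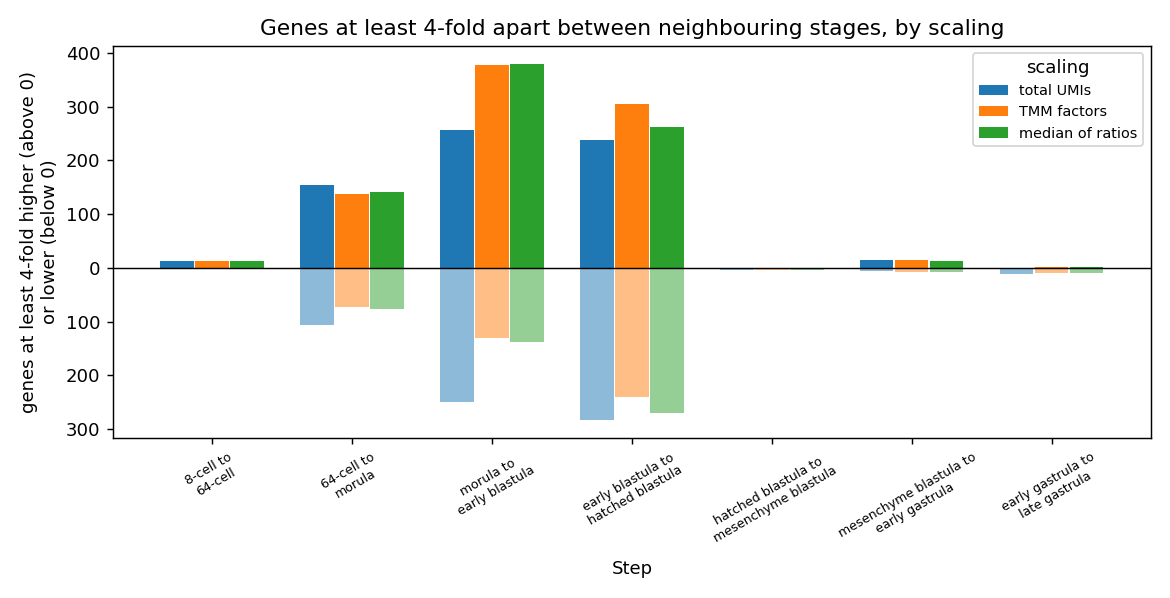
Number of genes at least 4-fold higher (above 0) and lower (below 0) at each step between adjacent stages, in bars for CPM, TMM and median-of-ratios scaling. From morula to early blastula the counts were 256 and 249 with CPM against 378 and 130 with TMM, and from hatched to mesenchyme blastula 0 and 3 with CPM.

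All 3 ribosomal protein genes rose at least 2-fold from morula to early blastula and again to hatched blastula. Among them, rps15a was already higher at morula, at 65.6 CPM against 30.5 CPM at 64-cell. The transcript of rps15a went from 46.6 CPM at 8-cell to 398 at early blastula and 4274 at late gastrula, 91.6-fold (85.1 to 98.8), and rps14 rose 121-fold (107 to 138), with a list median of 6.49 and 3 of 3 higher. Over the same interval the medians were 6.72 for skeletogenic genes (6 of 7 higher; 9.05 with unseen members at the floor), 7.45 for endoderm (5 of 5; 10.55), 6.96 for oral ectoderm (7 of 7; 8.97), 5.90 for aboral ectoderm (9 of 9; 8.23), 6.46 for the apical list (3 of 3; 8.71), 0.83 for blastocoelar genes (2 higher and 2 lower of 4; 1.91), 0.83 for the ciliary band (1 of 3 higher), and 0.38 for early zygotic genes (2 higher and 1 lower of 7; 0.63). Among lists with 1 measured gene, the log2 ratio was 4.66 for the pigment cell gene gcm (6.95 at the floor), -0.53 for the germline gene vasa, -0.01 for the egg gene ebr1, where TMM factors gave 0.50, -4.71 for Cdc6 of the maternal and cell cycle list and 2.93 for FoxJ1 of the ciliogenesis list. The signalling list had 1.27 (2.37 at the floor). Coelomocyte and sperm genes stayed low in every library: c3 (gene821) lay between 2.54 and 5.38 CPM, bf at or under 0.466 CPM and SPIH at or under 0.127 CPM.

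**Figure D3:**
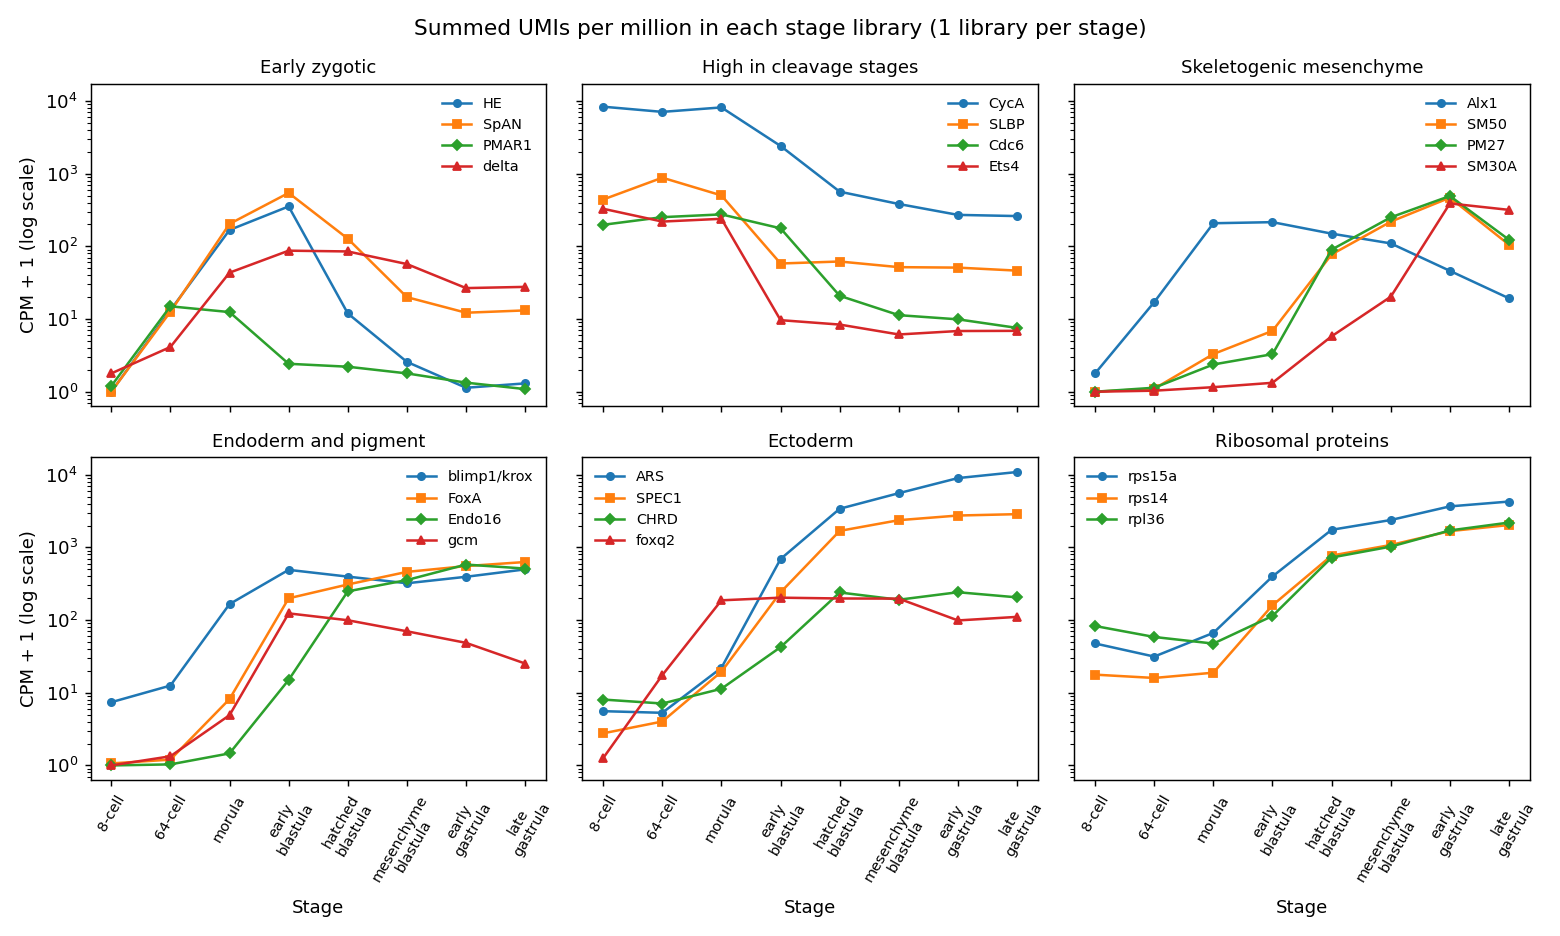
CPM plus 1 (log axis) of genes in 6 groups across the 8 stages, each point 1 library. HE peaked at early blastula with 353 CPM, SM30A reached 389 CPM at early gastrula and rps15a 4274 CPM at late gastrula.

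Clustering was used to ask which embryonic cell classes the libraries held. At late gastrula, 30.4% of 13000 cells resembled aboral ectoderm (95% Clopper-Pearson interval 29.7 to 31.3%), 14.7% oral ectoderm (14.1 to 15.4%), 11.9% endoderm (11.3 to 12.5%), 4.15% apical plate and neural cells (3.81 to 4.50%) and 1.04% skeletogenic mesenchyme (0.871 to 1.23%). The remaining 37.7% were in clusters that met no class. Under the alternatives, aboral ectoderm ranged from 20.9 to 35.1%, oral ectoderm from 11.8 to 16.1%, endoderm from 11.25 to 13.06% and apical plate from 4.04 to 7.01%. Genes that set a class apart, and so define it, were SM30A, SM50, LOC575608, PM27 and SM37 for skeletogenic cells, blimp1/krox with LOC589852, LOC591984, LOC575684 and LOC753678 for endoderm, CHRD, FoxG and Not with LOC577374 and LOC105445029 for oral ectoderm, hox1 with LOC577625, LOC578206, LOC105443529 and LOC762727 for aboral ectoderm, and foxq2 with LOC764367, LOC575604, LOC583193 and LOC583414 for the apical plate. An endoderm cluster of 156 cells had 82.1% of its cells in the highest doublet scores. With the main settings, pigment, coelomic pouch, germline and ciliary band classes could not be named at any stage. For the first 3 of these fewer than 3 markers were matched. In well 1 alone, 3.65% of late gastrula cells were named ciliary band.

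With the main settings, endoderm-like cells could be named from morula on, ectoderm from early blastula, and skeletogenic mesenchyme from hatched blastula. A missing name does not mean that such cells were absent. At early blastula, a cluster of 336 cells (5.25%) led by SpP19L, dri, Alx1, COLP3alpha and erg was not named skeletogenic. Nor was a morula cluster of 255 cells (6.89%) led by delta, Alx1, SpP19L, wnt1 and blimp1/krox. Both were picked out after their values were seen. Some of these names depended on the clustering: no endoderm was named at early blastula and no blastocoelar cells at mesenchyme blastula at resolution 0.5, and no oral ectoderm at early blastula with 4000 variable genes. Across all stages, 42 of 128 clusters were named, in 6 classes. No cluster of 8-cell or 64-cell embryos was named, and the unnamed share was 88.8% at morula, 72.2% at early blastula and 43.1 to 44.8% in the next 3 stages. Endoderm made up 11.2% of cells at morula, 10.0% at early blastula, 13.1% at hatched blastula, 12.2% at mesenchyme blastula and 12.2% at early gastrula. Aboral ectoderm went from 20.9% at hatched blastula (13.76 to 32.72% under the alternatives) to 19.7% and 24.4% in the following stages. Oral ectoderm stood at 12.4%, 10.4%, 10.4% and 8.75% from early blastula to early gastrula, and apical plate at 5.44%, 8.26%, 7.87% and 4.22%. Under the alternatives, aboral ectoderm ranged from 13.08 to 33.63% at mesenchyme blastula, apical plate from 5.438 to 11% at early blastula, 3.489 to 14.19% at hatched blastula and 4.557 to 11.38% at mesenchyme blastula, endoderm from 8.838 to 18.76% at morula and 6.559 to 15.70% at hatched blastula, and oral ectoderm from 8.523 to 16.50% at early gastrula. Skeletogenic mesenchyme made up 3.99% at hatched blastula (3.65 to 4.35%), 5.07% at mesenchyme blastula and 4.12% at early gastrula. With the minimum of 2475 UMIs, the early gastrula share was 1.58% (1.34 to 1.86%), because a skeletogenic cluster of 436 cells had a median of 1749.5 UMIs. Blastocoelar cells were 1.72% at mesenchyme blastula and 1.55% at early gastrula. With the main settings, no late gastrula cluster met that class, which sets no limit on the share of such cells. In well 1 alone, 6.73% of hatched blastula and 0.267% of late gastrula cells were named blastocoelar. Clusters kept out of a class by a strong marker of another class held 16.4% of cells at early blastula, 10.7% at hatched blastula, 6.60% at early gastrula and 4.99% at late gastrula.

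**Figure D4:**
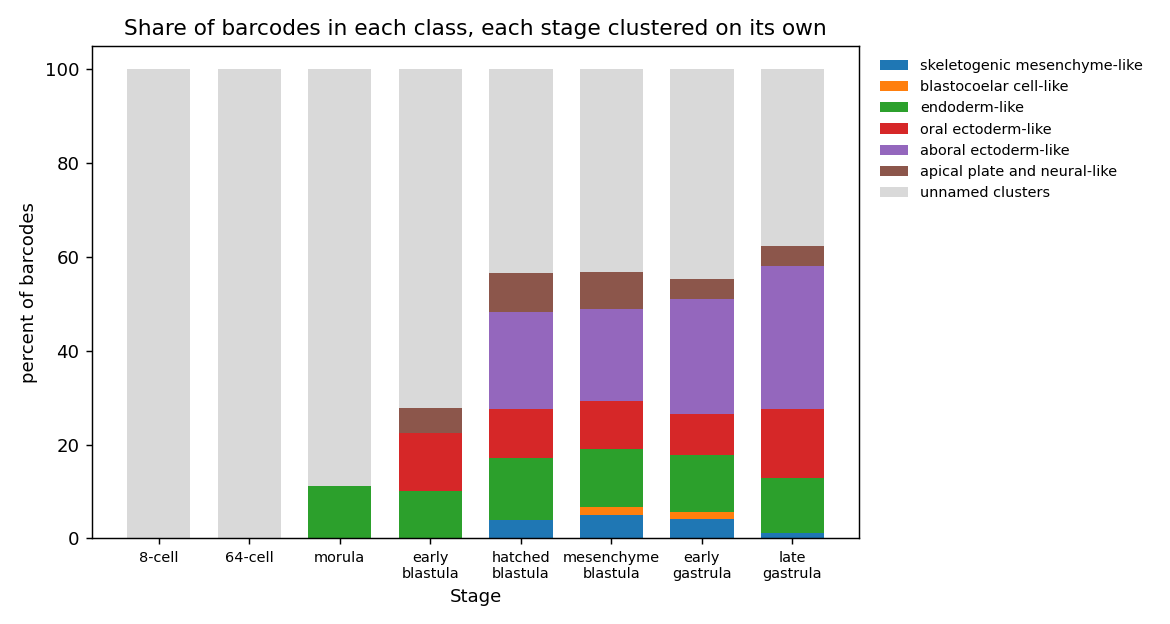
Percent of barcodes per class (stacked bars) at each stage, with unnamed clusters in grey. Aboral ectoderm reached 30.4% at late gastrula, and no cluster was named at 8-cell or 64-cell.

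Within classes, levels of several named genes differed between stages. Several of these genes were also markers used to name the classes, among them Alx1 and SM50 for skeletogenic cells and GATAc for blastocoelar cells. Their levels within a class thus depend partly on which clusters the naming rule admitted. In skeletogenic cells, Alx1 went from 2396 CPM at hatched blastula to 1746, 843 and 445 CPM in the next stages, and erg from 2400 to 340 CPM, while SM30A went from 88.0 to 374, 10869 and 15704 CPM. SM50 in the same cells had 1467, 4334, 13157 and 5124 CPM. With the minimum of 2475 UMIs, SM50 at early gastrula was 6792 CPM and SM30A 6205 CPM. In aboral ectoderm, ARS went from 5215 to 18404 CPM and SPEC1 from 3271 to 6096 CPM between hatched blastula and late gastrula, while Lim1 went from 503 to 51.4 CPM and Tbx2/3 from 741 to 362 CPM. In endoderm, Endo16 went from 78.1 CPM at early blastula to 1806 CPM at late gastrula and GATAe from 340 to 1064 CPM, while eve went from 1766 CPM at morula to 83.2 CPM. In oral ectoderm, dri went from 1.63 CPM at early blastula to 56.8 at mesenchyme blastula, 1135 at early gastrula and 2469 CPM at late gastrula, and FoxG from 4.17 to 666 CPM. Apical plate cells had foxq2, which also served to name them, between 1372 and 2121 CPM, and NK2.1, a homeobox gene of the apical plate, went from 131 to 1204 CPM. In blastocoelar cells GATAc went from 2026 to 822 CPM and erg from 663 to 1679 CPM between mesenchyme blastula and early gastrula. ARS was also read in skeletogenic cells, at 6237 CPM at late gastrula.

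The share of cells with a UMI of a marker, at an equal 1000 UMIs per cell, traced where regulators were detected. Cells with a dri UMI went from 3.96% at mesenchyme blastula to 21.0% at early gastrula and 38.2% at late gastrula (37.4 to 39.1%), against 1.28%, 7.66% and 10.7% of endoderm cells, and without thinning from 8.83% to 37.9% and 57.8% of cells. Alx1 was found in 14.2% of morula cells, 9.06% at early blastula, 5.71% at mesenchyme blastula, 3.57% at early gastrula and 1.23% at late gastrula (1.05 to 1.44%). Of aboral cells, 1.37%, 1.82% and 0.859% had an Alx1 UMI in the last 3 of these stages, and at morula and early blastula no aboral class was named for comparison. Unthinned, the morula and late gastrula shares of Alx1 were 36.4% and 3.85%. The pigment cell gene gcm went from 0.378% at morula to 448 of 6400 cells at early blastula and then to 4.07%, 3.32% and 1.78% from mesenchyme blastula on, with 0.624 to 0.632% of aboral cells as background, and unthinned from 3.59% to 14.2%, 7.91%, 6.75% and 4.87%. FoxA was found in 12.02% of early blastula cells and 27.9% at late gastrula (45.9% unthinned), with 10.3% of aboral cells. FoxG went from 610 of 12200 cells to 11.05% between mesenchyme blastula and late gastrula (endoderm 1.15% and 2.07%; unthinned 12.3% and 20.7%). For foxq2 the shares were 12.03% at morula and 5.82% at late gastrula (endoderm 1.94% and 1.75%; unthinned 31.4% and 11.5%). Tbx2/3 went from 0.359% of early blastula cells to 32.0% of hatched blastula cells (2.41% and 57.2% unthinned), but 35.1% of endoderm cells had a UMI too, so it did not separate classes there.

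MTa, a metallothionein, was among the named genes that varied most between cells at every stage, with Fano factors from 1.903 at morula to 18.44 at hatched blastula. At 8-cell, MTB1 had a Fano factor of 44.2, egf1 of 9.92 and rps15a of 7.57. At morula, Alx1 led with 2.63, followed by eve with 2.23 and foxq2 with 2.08. At early blastula MTa had 7.753 and SpP19L 7.737, and SpP19L led with 22.2 at hatched blastula and 18.78 at mesenchyme blastula, and spicule matrix genes were also listed, with PM27 at 14.0 and SM50 at 12.5 at mesenchyme blastula and SM30A at 27.2 at early gastrula and 21.7 at late gastrula. In 950 cells per stage, the genes above the limit numbered 114 of 3408 at 8-cell, 97 of 3595 at 64-cell, 28 of 3256 at morula, 108 of 3027 at early blastula, 302 of 2788 at hatched blastula, 332 of 2746 at mesenchyme blastula, 301 of 2812 at early gastrula and 211 of 2627 at late gastrula.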

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

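Tests chosen only after the data had been seen were the minimum of 2475 UMIs, the highest 5% of doublet scores left out and the 64-cell library without 42 barcodes; the others were fixed earlier. Which results count as answers to a comparison was widened after these alternatives had been run, and list medians were called moved when they differed from the reported log2 value by more than 0.58, which is 1.5-fold, a limit set after the lists were seen. The direction of single genes called 4-fold was not compared between the alternatives. Among lists with at least 3 measured genes, no median of at least 2-fold changed sign in these recomputations. Some list medians near 0 and SM30A between early and late gastrula, neither of them called, did so, with part of the values given in the report. The blastocoelar median from morula to early blastula, for example, went from 0.06 to -0.26 with a pseudocount of 5 CPM. No paired analysis was possible because each stage had 1 library and nothing linked embryos between stages.

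Counts of genes at least 4-fold higher or lower stayed within 1.5 times the reported count in 108 of 152 recomputations. All deposited barcodes are not among these, because the filter of 200 genes removed none and the counts were the same ones. Some of the 152 could not move either. The minimum of 2475 UMIs left out no barcode at 8-cell, 64-cell, morula and late gastrula, so comparisons between those stages stayed the same. At least 1000 genes per barcode left out none at 8-cell, morula and early blastula. Lowering the minimum admits more genes by construction. With a minimum of 10 CPM, the counts were 41 higher and 1 lower from 8-cell to 64-cell, 404 higher and 191 lower from 64-cell to morula, 385 higher and 553 lower from morula to early blastula, 581 higher and 591 lower from early blastula to hatched blastula, 2 higher and 5 lower from hatched blastula to mesenchyme blastula, 47 higher and 13 lower from mesenchyme blastula to early gastrula, 8 higher and 22 lower from early gastrula to late gastrula and 1788 higher and 2004 lower from 8-cell to late gastrula. With no minimum, they were 59 higher and 6 lower from 8-cell to 64-cell, 593 higher and 205 lower from 64-cell to morula, 424 higher and 632 lower from morula to early blastula, 801 higher and 720 lower from early blastula to hatched blastula, 4 higher and 5 lower from hatched blastula to mesenchyme blastula, 69 higher and 14 lower from mesenchyme blastula to early gastrula, 9 higher and 25 lower from early gastrula to late gastrula and 2562 higher and 2301 lower from 8-cell to late gastrula. TMM factors gave 130 lower from morula to early blastula, 1 higher from early gastrula to late gastrula and 651 lower from 8-cell to late gastrula. Median-of-ratios factors gave 138 lower from morula to early blastula and 1 higher from early gastrula to late gastrula. The mean of each cell's CPM gave 1 higher from hatched blastula to mesenchyme blastula and 25 lower from early gastrula to late gastrula. Each well alone gave 4 and 1 higher from early gastrula to late gastrula, and a pseudocount of 5 CPM gave 7 lower in that step. At least 1000 genes per barcode, and the minimum of 2475 UMIs, each gave 0 lower there, and both leave out shallow barcodes. Apart from the lowered minimum and the left-out barcodes, the cause was not tested. The steps from hatched to mesenchyme blastula and from early to late gastrula had few genes, so a change of a few moved them past 1.5 times.

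Medians of lists with at least 3 measured genes stayed within the limit in 128 of 144 recomputations. Smaller lists were not counted. From 8-cell to late gastrula, for example, a pseudocount of 5 CPM gave 0.37 in place of 1.27 for signalling and 2.55 in place of 4.66 for gcm. TMM factors are not among these, because they shifted the median of all genes by at most 0.51 and so could hardly pass the limit. Part of the 144 could not move either, since the minimum of 2475 UMIs left out no barcode at 8-cell, 64-cell, morula and late gastrula. Medians of comparisons between those stages were therefore the same ones. A pseudocount of 5 CPM shrinks ratios of genes near the floor by construction. From 64-cell to morula it gave 0.31 for skeletogenic mesenchyme, 1.23 for endoderm, 0.89 for oral ectoderm and 0.52 for apical plate. From 8-cell to late gastrula it gave 4.45 for skeletogenic mesenchyme, 0.21 for blastocoelar cells, 5.46 for endoderm, 4.98 for oral ectoderm, 3.67 for aboral ectoderm and 4.45 for apical plate. From morula to early blastula it gave 1.80 for endoderm and 1.18 for apical plate. From early blastula to hatched blastula it gave 0.85 for oral ectoderm. From 8-cell to 64-cell it gave 1.13 for early zygotic. With the minimum of 2475 UMIs, the skeletogenic median was 0.29 from mesenchyme blastula to early gastrula and -0.74 from early gastrula to late gastrula, since 369 of 618 and 149 of 535 skeletogenic cells of mesenchyme blastula and early gastrula passed that minimum.

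Shares of cells at late gastrula stayed within their counting intervals in 27 of 45 recomputations, and shares at earlier stages in 75 of 181. The 27 include 5 with the minimum of 2475 UMIs, which left out no late gastrula barcode and so could not move a share there. The late gastrula skeletogenic share lay between 0.933% and 1.14% under all alternatives. All of them start from a library without barcodes under 2475 UMIs, so they cannot show whether shallower skeletogenic cells are missing from it. The values that moved follow, and the cause was not tested, except that the minimum of 2475 UMIs and that of 1000 genes leave out shallower barcodes. At resolution 0.5, endoderm made up 18.8% at morula, 0% at early blastula, 11.6% at hatched blastula, 15.7% at mesenchyme blastula and 8.12% at early gastrula. Apical plate stood at 11% at early blastula, 11.4% at mesenchyme blastula and 4.54% at late gastrula. Oral ectoderm accounted for 8.19% at early blastula and 11.7% at early gastrula. The aboral ectoderm share was 32.7% at hatched blastula, 33.6% at mesenchyme blastula and 35.1% at late gastrula. Skeletogenic mesenchyme stood at 5.22% at hatched blastula. Blastocoelar cells accounted for 0% at mesenchyme blastula. At resolution 2, endoderm stood at 8.84% at morula, 11.2% at early blastula, 12.2% at hatched blastula, 10.3% at mesenchyme blastula, 10.4% at early gastrula and 12.7% at late gastrula. Apical plate accounted for 9.09% at early blastula and 6.79% at mesenchyme blastula. The oral ectoderm share was 5.52% at early blastula, 11.97% at mesenchyme blastula and 12.6% at late gastrula. Aboral ectoderm stood at 18.99% at hatched blastula, 13.1% at mesenchyme blastula, 18.8% at early gastrula and 20.9% at late gastrula. Skeletogenic mesenchyme accounted for 5.37% at hatched blastula and 4.33% at mesenchyme blastula. The blastocoelar cells share was 3.21% at mesenchyme blastula. With 4000 variable genes, endoderm accounted for 13.8% at morula, 11.6% at early blastula, 10.6% at hatched blastula and 15.98% at mesenchyme blastula. The oral ectoderm share was 0% at early blastula, 16% at early gastrula and 13.1% at late gastrula. Aboral ectoderm stood at 14.1% at hatched blastula, 17.2% at mesenchyme blastula and 26.8% at late gastrula. Apical plate accounted for 8.77% at hatched blastula and 4.56% at mesenchyme blastula. Without the doublets that Scrublet marked, endoderm made up 14.2% at morula, 12.2% at early blastula, 10.5% at hatched blastula and 10.3% at mesenchyme blastula. Apical plate stood at 7.16% at early blastula, 7.07% at hatched blastula and 5.09% at mesenchyme blastula. Oral ectoderm accounted for 8.72% at hatched blastula, 9.77% at mesenchyme blastula and 9.34% at early gastrula. The skeletogenic mesenchyme share was 5.32% at hatched blastula. Aboral ectoderm stood at 14.6% at mesenchyme blastula and 33.6% at late gastrula. With at least 1000 genes per barcode, aboral ectoderm stood at 13.8% at hatched blastula, 21.7% at mesenchyme blastula and 28.3% at early gastrula. Apical plate accounted for 3.49% at hatched blastula and 6.23% at mesenchyme blastula. The endoderm share was 15.1% at hatched blastula, 10.1% at early gastrula and 12.8% at late gastrula. Oral ectoderm stood at 11.5% at hatched blastula and 9.85% at early gastrula. Skeletogenic mesenchyme accounted for 5.64% at hatched blastula, 3.92% at mesenchyme blastula and 2.046% at early gastrula. In well 1 alone, aboral ectoderm accounted for 19.2% at hatched blastula, 14.9% at mesenchyme blastula, 17.5% at early gastrula and 28.8% at late gastrula. The apical plate share was 6.56% at hatched blastula, 5.58% at mesenchyme blastula, 3.66% at early gastrula and 5.23% at late gastrula. Endoderm stood at 15.7% at hatched blastula, 15.6% at mesenchyme blastula and 9.43% at early gastrula. Oral ectoderm accounted for 11.8% at hatched blastula, 11.2% at mesenchyme blastula, 16.5% at early gastrula and 11.8% at late gastrula. The blastocoelar cells share was 2.42% at mesenchyme blastula. Classes without cells in the main settings also appeared in this well, and the recomputations above do not count them. They were blastocoelar cells at hatched blastula (6.73%) and late gastrula (0.267%), and ciliary band at late gastrula (3.65%). Skeletogenic mesenchyme stood at 3.73% at early gastrula. In well 2 alone, aboral ectoderm made up 21.8% at hatched blastula, 14.4% at mesenchyme blastula and 33.4% at late gastrula. Apical plate stood at 14.2% at hatched blastula, 4.6% at mesenchyme blastula, 3.33% at early gastrula and 7.014% at late gastrula. Endoderm accounted for 6.56% at hatched blastula, 10.9% at mesenchyme blastula and 13.1% at late gastrula. The oral ectoderm share was 7.72% at hatched blastula, 11.7% at early gastrula and 16.1% at late gastrula. Skeletogenic mesenchyme stood at 5.14% at hatched blastula. Blastocoelar cells accounted for 1.18% at mesenchyme blastula and 1.32% at early gastrula. With the minimum of 2475 UMIs, aboral ectoderm stood at 26.1% at hatched blastula, 22.9% at mesenchyme blastula and 30.7% at early gastrula. Apical plate accounted for 9.07% at hatched blastula, 9.22% at mesenchyme blastula and 5.07% at early gastrula. The endoderm share was 14.97% at hatched blastula, 14.3% at mesenchyme blastula and 13.98% at early gastrula. Oral ectoderm stood at 12.4% at hatched blastula, 11.9% at mesenchyme blastula and 9.56% at early gastrula. Skeletogenic mesenchyme accounted for 4.59% at hatched blastula, 3.89% at mesenchyme blastula and 1.58% at early gastrula. The blastocoelar cells share was 2.08% at mesenchyme blastula. Without the highest 5% of doublet scores, aboral ectoderm accounted for 21.7% at hatched blastula and 31.7% at late gastrula. The skeletogenic mesenchyme share was 4.66% at mesenchyme blastula. Endoderm stood at 11.2% at late gastrula. Where a share was 0, no cluster met the class, which sets no limit on the share of such cells.

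The numbers of variable genes stayed within 1.5 times in 18 of 33 recomputations, among them all with the highest 5% of doublet scores left out or without the 42 barcodes. Thinning to 2000 UMIs, which lets more genes pass the mean of 0.05 UMI, gave 281 at 8-cell, 164 at 64-cell, 50 at morula, 200 at early blastula, 576 at hatched blastula, 591 at mesenchyme blastula, 488 at early gastrula and 489 at late gastrula. A Fano factor of 2, a stricter limit, gave 52 at 8-cell, 17 at morula, 59 at early blastula, 163 at hatched blastula, 182 at mesenchyme blastula, 149 at early gastrula and 100 at late gastrula. Shares of cells with a marker UMI followed depth by construction, and 355 of 432 moved past their intervals when thinned to 2000 UMIs or not thinned. Within classes, 1189 of 1273 values stayed within their intervals with the minimum of 2475 UMIs, counting stages where it left out cells of the class, and SM50 in skeletogenic cells at early gastrula was among those that moved, from 13157 to 6792 CPM. Without the doublets that Scrublet marked, 310 of 335 late gastrula values did, and the earlier stages from early blastula on had almost no cells left out. Depth limited the smallest values: at 8-cell, a gene under 0.196 CPM lay below the floor.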

Other observations

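Tests chosen only after the result was seen were those on the number of captured skeletogenic cells, on the wells, on barcode swapping and on free RNA; for the UMI minimum and for RNA loss from damaged cells, the expected outcomes were written before the test was run, although the minimum itself was chosen after the data had been seen. The genes and clusters described here were picked out after their values were seen. At each stage from early blastula, gcm was highest in 1 cluster, although too few pigment cell markers were matched to name the class. That cluster held 2.78% of cells at early blastula, 5.31% at hatched blastula, 4.30% at mesenchyme blastula, 2.82% at early gastrula and 2.39% at late gastrula (2.14 to 2.67%). Its gcm level was 1464, 907, 940, 849 and 536 CPM, against 81.1, 38.8, 14.4, 17.7 and 11.2 CPM in the other cells. At early blastula the cluster held 1892 of 5262 gcm UMIs, and GATAe and Endo16 led beside gcm. At hatched blastula it was led by prox1, gcm and GATAc, of which prox1 and GATAc are blastocoelar markers.

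Nanos2, a germline gene, was concentrated in a small cluster at morula, with 155 CPM in 120 cells (3.24%) against 3.51 CPM elsewhere, and Alx1 and delta led the same cluster. At early blastula 122 cells (1.91%) had 159 CPM of Nanos2 against 0.518 CPM. From mesenchyme blastula on vasa led that cluster, which held 1.57% of cells there and 1.65% at early gastrula; at late gastrula the cluster with the highest Nanos2 rested on 3 UMIs. In 64-cell embryos, a cluster of 147 cells (14.7%) was led by PMAR1, Alx1, eve and blimp1/krox, genes of the vegetal pole. A hatched blastula cluster of 175 cells still carried the cleavage-stage genes Ets4, CycA, Cdc6 and SLBP. At 8-cell, 120 cells (12.6%) with a median of 7007.5 UMIs were led by secretory genes such as DVR1 and ebr1, and 112 cells were led by rps15a, CyI and MTB1.

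Skeletogenic transcripts were lower at late than at early gastrula. Part of this fall may come from the higher UMI minimum of the late gastrula library: with that minimum in both, SM50 was 1.667-fold higher at early gastrula (1.606 to 1.730), against 4.481-fold without it, a value between the bounds set beforehand for and against this cause. If fewer skeletogenic cells had been captured with no change inside them, levels within the class would match, and the median within-class ratio of 5 genes was 1.326, which leaves that open. SM30A went the other way within the class, at 0.395, while msp130 was at 1.566, so the genes did not move alike. A biological change between the stages stays open and untested, since stage and library cannot be told apart.

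Mesenchyme blastula had skeletogenic clusters led by SM50 and by Alx1, with median UMIs of 1501 and 3805. They did not hold all 618 skeletogenic cells of that stage, and the others are not part of this contrast. Loss of cytosolic RNA from damaged cells may explain this split, but the test could not tell it from a later state. The leading genes of the low-UMI 8-cell cluster were higher in the SM50-leading cells, with a median log2 ratio of 0.92 over 77 measured genes. This was above all matched random lists, and 33 of them were at least 2-fold higher against 1 lower, as set beforehand for RNA loss. However, the 8-cell cluster was not shown to be damaged. Its leading genes were secretory, and a state with more secretory transcripts could raise them too. In the SM50-leading cells the ribosomal protein gene rps14 was lower, at a ratio of 0.423, and Alx1 at 0.398, while SM50 was at 3.89. The wells differed in composition, with 116 SM50-leading and 86 Alx1-leading cells in well 1 against 56 and 239 in well 2. Within each well the same 77 genes, which were not chosen by SM50, had median log2 ratios of 0.87 and 0.84. The lower bootstrap limit over genes was 0.50 in both, where about 0 had been set for a difference between wells alone. The clusters were formed by expression over both wells together, so a difference between them inside each well was likely in any case. This test therefore cannot exclude the composition of the wells as a cause, although both clusters occurred in both wells. A first test on SM50 was set aside because SM50 names the cluster. A later state of the same lineage was not tested and stays open.

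In the 64-cell library, 42 barcodes (4.20%) carried blastula genes such as SpAN, HE and VEB4, with a median of 14167.5 UMIs against 33341 in the others. Barcode swapping is unlikely, as 0% of these barcodes were shared with the morula or early blastula library (0 of 42, with a Clopper-Pearson upper limit of 8.408%). For free RNA of blastula cells, the first test asked whether CycA and SLBP stayed within 1.5 times of the other 64-cell barcodes, and they did, at 1.150-fold (1.113 to 1.189) and 1.153-fold (1.051 to 1.269) lower, as free RNA would require; SLBP was 1.755-fold lower at morula than at 64-cell, a fall these barcodes did not show. A second test was added after that result, and there the 107 genes lower at morula had a median log2 ratio of -2.23 (bootstrap interval -2.37 to -2.14), against free RNA. Morula itself had -2.48 for those genes, and across genes, which are not independent replicates, the 42 barcodes correlated with morula at a rho of 0.949 and with 64-cell at 0.831. Embryos that ran ahead, or a mixed sample, were not tested and stay open.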
